A study of Arabidopsis thaliana with 6 samples.

How the data were processed

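RNA was measured in whole Arabidopsis thaliana seedlings collected 7 days after stratification, in 3 biological replicates of wild-type Col-0 and 3 of an sqtl1 RNA interference (RNAi) line. The sample names of the RNAi replicates carry the mark sh1, whose meaning is not given in the sources used here. Per the labels' protocols, seedlings were grown in long days on half-strength MS medium with sucrose and agar, poly(A) RNA was captured on oligo(dT) beads, and strand-marked Illumina TruSeq libraries were sequenced as paired reads. Per the submitters' processing notes, the tools named are Trimmomatic 0.39 and Bowtie2 2.2.6 and the genome build is TAIR10. The roles of these tools, the gene set, the counting tool, the use of strand in counting and the treatment of reads that map to several places are not given in the sources used here.

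The values are RPKM (reads scaled by gene length in kilobases and by mapped reads of the library) as deposited by the authors, printed to 2 decimals. The deposited table also gives, for each gene, a length in kilobases and, per the file headers, a weighted multiple-mapping ratio, a fraction between 0 and 1 that is read here as the share of a gene's reads mapping to more than 1 place. Of 38199 lines in the table, 38194 carried a gene and 5 did not and were left out. Every column of sample values matched 1 sample. RPKM times length summed to between 926820 and 1071469 per library, with a geometric mean of 1000199, which is the pattern left by scaling factors between libraries whose product is 1. No source used here states such a step.

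Genes shorter than 0.4 kb were used to look for the step that 1 read is worth. Between 93.7% and 94.9% of low values lay on a step within 0.0055 RPKM, after an offset of 0.25 reads per gene. The estimated depth from these steps was 48.0, 38.0 and 49.9 M (mega) reads for Col-0 replicates 1 to 3 and 43.7, 46.9 and 43.9 M for the RNAi replicates. The unit may be a read or a read pair. Genes without a read hold a small value that depends on their length and is 0 where it rounds to 0 at 2 decimals. These depths are estimates and were used for an alternative with weights, for floors of 3 reads per library and for the check for duplicate libraries, which found none.

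Groups were compared with limma 3.58.1 in R 4.3.3 on log2(RPKM + 1), with a moderated test whose variance prior followed mean expression, over the 19458 genes with a mean of at least 1 RPKM over all 6 libraries. Calls are at a Benjamini-Hochberg adjusted p under 0.05. Log2 fold changes are on the log2(RPKM + 1) scale, which understates the change of low genes, whereas ratios are between group means of RPKM. Exceptions are values from the floors of 3 reads, the other pseudocounts and the voom weights. Errors beside means are SDs over n = 3 libraries. In the text, every adjusted p of a gene is from limma. Data were simulated for the comparison of sqtl1 RNAi with Col-0, with the estimated library sizes and with the Col-0 means for both groups. The RNAi means did not enter, so genes low in Col-0 and high in the RNAi line are not represented. Over 19190 genes, the step recovered 0 of 47 genes changed by 1.25-fold, 31 of 49 changed by 1.5-fold, 47 of 49 changed by 2-fold and 50 of 50 changed by 4-fold. Of its 133 calls, 5 were false. With no gene changed it called 0 of 19184 genes and 0 of 38 lists. The simulation drew each gene independently, with the same dispersion for all genes of a group. Members of a list did not move together in it, whereas in the data the estimated correlation reached 0.98 for the photosystem list. The 0 lists are therefore no check of camera's calls.

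Gene lists for pathways, hormones, nutrition, stress, organs, cell types and organelle genomes were fixed before the data were examined. Of 852 entries, 831 matched their identifier in the RefSeq gene table of TAIR10.1 and 21 were left out. Of the 38194 gene identifiers, 37898 were in that table, which also gave gene symbols and coordinates. Coordinates are therefore those of TAIR10.1. Lists with at least 5 tested genes were tested with camera in limma at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the 39 lists. Camera with an estimated correlation and fry were run beside it. Lists chosen after the data were seen were adjusted over those 5 lists alone, and tests of transcript classes over their 8 p values. Members past the gene test were counted over all genes tested and adjusted over the list alone.

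Genes are named by a rule set in advance. Among genes past the threshold with at least 5 RPKM in the higher group and no overlap between groups, it takes the 15 with the largest increase and the 15 with the largest decrease. It adds up to 4 members per called list in the list's direction, up to 3 members of each other list with at least 3 members past the test, and 4 reference genes. For 1 gene that the rule takes, the result is not reported here. Genes outside the rule are said to be chosen after their values were seen. No label or table used here gives an identifier for SQTL1, so the RNAi target was not analysed here.

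Alternatives were pseudocounts of 0.1 and 5, no filter and a filter at 5 RPKM, median-of-ratios rescaling, quantile normalization, no variance trend, a robust variance prior, library weights, a replicate block and leaving out each library. Weights from voom on the estimated reads were added after seeing the data. Annotation terms were tested with Fisher's exact test (one-sided), over 245 terms of at least 10 genes among tested genes that carry a term. Scripts also used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.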

Results

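Gene expression was compared between whole seedlings of an sqtl1 RNAi line and of wild-type Col-0, the reference accession of Arabidopsis thaliana. Each group held 3 biological replicates, collected 7 days after stratification. The estimated depth ranged from 38.0 to 49.9 M reads per library in Col-0 and from 43.7 to 46.9 M in the RNAi line. Between 19143 and 19384 genes per library reached 1 RPKM. The identifier of the RNAi target is not given in the sources used here, so its knockdown was not analysed here.

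The 2 genotypes differed over much of the transcriptome. Of 19458 genes tested, 4894 were higher and 5346 were lower in the RNAi line (limma adjusted p under 0.05), together 52.6% of the genes tested. A change of at least 1 log2 unit was found for 653 higher and 634 lower genes. The 3 values of each group did not overlap for 64.1% of genes tested, where chance gives 10%. The first principal component held 82.4% of the variance and separated the groups. The Col-0 libraries scored between -38.8 and -36.9 on it. The RNAi libraries were spread more widely, with scores of 49.8, 42.6 and 21.7, and replicate 3 lay nearest to Col-0. The median SD of a gene between libraries was 0.057 log2 units in Col-0 and 0.111 in the RNAi line. The counts by fold limit depended on the pseudocount: with a pseudocount of 5 they were 238 higher and 281 lower.

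**Figure D1:**
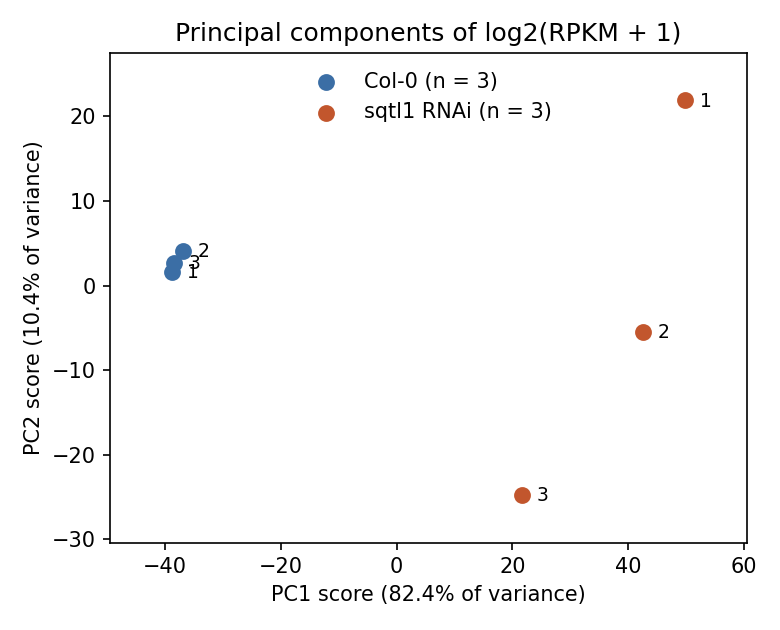
Scores of the 6 libraries on the first 2 principal components of log2(RPKM + 1), with the percentage of variance on each axis and the replicate number beside each point. The 3 Col-0 libraries lie together near -38.8 to -36.9 on the first component, and the RNAi libraries lie at 49.8, 42.6 and 21.7.

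Among the genes with the largest increases were a MATE efflux transporter gene, the transcription factor gene NAC044, and isocitrate lyase (ICL) and malate synthase (MLS), the 2 enzymes specific to the glyoxylate cycle. AT2G04050, the MATE gene (chromosome 2, 1337180 to 1339468), rose from 0.0733 ± 0.0153 to 57.3 ± 26.2 RPKM, a log2 fold change of 5.65 (SE 0.33, adjusted p = 0.000151). NAC044 (AT3G01600, chromosome 3, 229075 to 231517) rose 78.0-fold, from 0.803 ± 0.146 to 62.6 ± 13.1 RPKM (adjusted p = 2.57e-05). ICL (AT3G21720) rose from 3.60 ± 2.33 to 167 ± 104 RPKM, and MLS (AT5G03860) from 3.08 ± 0.702 to 91.5 ± 75.3 RPKM. The neighbouring genes AT2G18190 and AT2G18193, both annotated as P-loop nucleoside triphosphatases, rose to 23.5 ± 10.2 and 76.1 ± 29.0 RPKM. AT2G47780, a rubber elongation factor family gene, rose from 0.597 ± 0.403 to 84.9 ± 47.8 RPKM. AT5G13210, AT1G17960, annotated as a threonyl-tRNA synthetase, and the jacalin lectin gene AT1G33790 rose 37.0-fold, 19.3-fold and 17.2-fold. LCR67, which encodes a small cysteine-rich protein, rose 39.2-fold, and the late embryogenesis abundant gene AT3G02480 rose 17.5-fold. A nuclear 5.8S ribosomal RNA gene, AT2G01020 (chromosome 2, 5782 to 5945), rose 11.6-fold, from 147.5 ± 20.4 to 1704 ± 63.9 RPKM. The share of its reads given as mapping to several places was 0.975, so its level could not be assigned to 1 copy.

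The largest decreases included 2 thionin genes, which encode small antimicrobial peptides, and a run of lipid-transfer protein genes on chromosome 4. The thionin gene AT1G66100 fell from 25.2 ± 1.5 to 0.657 ± 0.251 RPKM, 38.4-fold lower (log2 fold change -3.99, SE 0.12, adjusted p = 2.57e-05). THI2.2 was 10.2-fold lower. The lipid-transfer genes AT4G22485, AT4G22505, AT4G22513, AT4G22517 and AT4G22520 lie between positions 11844506 and 11858970 of chromosome 4 and were between 9.48-fold and 26.9-fold lower. MLP328, a major latex protein-like gene, fell from 795 ± 62.4 to 120 ± 41.7 RPKM. AT3G05727, annotated as a pollen coat protein family member, fell 18.4-fold, and AT2G33850, an E6-like gene, fell 13.5-fold. The beta-glucosidase gene BGLU18 fell 9.55-fold, the fatty acid desaturase gene AT1G06360 fell 10.3-fold and the methyl esterase gene MES18 fell 12.5-fold. The cytochrome P450 gene AT5G36130 fell 11.1-fold, and FRO6, a ferric reductase of shoots, fell 7.13-fold. All 15 genes had an adjusted p of 0.00104 or less in limma.

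Photosynthesis genes of the nucleus and a part of the plastid genome were lower. All 37 nuclear genes of the photosystems and light-harvesting antennae tested were lower, with a median log2 fold change of -1.098 (camera adjusted p = 4.76e-09). LHCB2.3 fell from 376 ± 19.2 to 98.0 ± 49.6 RPKM, LHCA4 from 4076 ± 205 to 1450 ± 518, LHCB2.1 from 1077 ± 137 to 405.5 ± 122 and PSBQ-2 from 1066 ± 38.0 to 509.6 ± 144. All 18 chlorophyll biosynthesis genes were lower (median -0.66, camera adjusted p = 1.94e-07), among them HEMA1, the first committed enzyme of tetrapyrrole synthesis, at 111 ± 3.13 against 73.4 ± 2.11 RPKM, and HEMC, HEME2 and the magnesium chelatase subunit gene CHLI2, which were 1.81-fold, 1.61-fold and 1.67-fold lower. All 17 Calvin cycle genes were lower (median -0.74, camera adjusted p = 9.13e-06), with RPE 2.16-fold, FBA2 1.91-fold, GAPA-2 1.85-fold and TIM 1.74-fold lower. Of 88 genes of the plastid genome, 49 were lower and 2 higher (camera adjusted p = 5.41e-06). They included ATCG00730, a gene of photosynthetic electron transfer, at 8.65 ± 0.209 against 3.11 ± 0.696 RPKM, and 3 transfer RNA genes. ATCG00940 was at 288 ± 35.5 against 113 ± 15.1, with a share of reads mapping to several places of 0.997. ATCG00980 and ATCG01150 were listed with equal values, 5.39 ± 0.850 against 1.40 ± 0.0945, and all their reads map to several places, so they count 1 signal 2 times. Plastid-encoded reads made up 0.699% to 0.760% of Col-0 libraries and 0.239% to 0.410% of RNAi libraries. The plastid values are of RNA that passed poly(A) capture and may not follow the levels of plastid transcripts. Adjusted over the list alone, the counts were 37, 18, 17 and, for the plastid genome, 50 lower and 2 higher. None of these 4 lists was called with an estimated correlation (adjusted p = 0.596 for each). With no filter on low values, 18 of the 37 photosystem genes and 11 of the 17 Calvin cycle genes were past the threshold, and with quantile normalization 11 of the 17 Calvin cycle genes were. Quantile normalization also moved the log2 fold change of LHCA4 from -1.55 to -0.88 (adjusted p = 0.0128).

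Seed storage and late-embryogenesis genes moved the other way. Of 14 tested, 13 were higher and none was lower, with a median log2 fold change of 2.61 (camera adjusted p = 0.000211, adjusted p = 0.596 with an estimated correlation), and the count was 13 adjusted over the list alone. For 2 members no read was estimated in a group. Their change was also taken as the log2 ratio of mean RPKM to a floor of 3 reads per library, without the added 1. The median was then 2.75. This median mixes 2 scales, so its excess over 2.61 is not a larger effect. The levels were low and varied between RNAi libraries. The albumin gene SESA1 was at 0.0200 ± 0.0173 RPKM in Col-0 and at 37.5, 7.87 and 6.01 in RNAi replicates 1 to 3. SESA5 was at 35.2, 13.5 and 4.09 RPKM and the cruciferin gene CRA1 at 28.0, 7.62 and 5.18. PER1, a seed peroxiredoxin, rose from 0.130 ± 0.0656 to 7.04 ± 4.15 RPKM. LTP2, a lipid transfer protein gene that Col-0 seedlings expressed at 35.7 ± 8.14 RPKM, rose 9.49-fold. With voom weights on the estimated reads, chosen after seeing the data, SESA1, SESA5 and CRA1 no longer passed the threshold (adjusted p = 0.0769, 0.0826 and 0.0606), although their log2 fold changes were larger (8.97, 7.01 and 7.69 against 3.71, 3.63 and 3.27). Without Col-0 replicate 1, and likewise without Col-0 replicate 3, 8 of 16 members were past it. Apart from LTP2, the higher members lay under 1 RPKM in Col-0 and entered the test through their RNAi values. With no filter, 7 of all 24 members were higher and none lower, with a median of 1.37, and with a filter at 5 RPKM 6 of 6 were higher.

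Shoot meristem genes were among the hormone and development groups that rose. Of 22 genes of shoot meristem and leaf development, 13 were higher and 5 lower (camera adjusted p = 0.0225, 0.596 as adjusted p with an estimated correlation). The class I KNOX genes STM, KNAT1 and KNAT2, which act in the undifferentiated meristem, rose 7.22-fold, 5.64-fold and 4.79-fold, with STM at 1.74 ± 0.189 against 12.6 ± 2.00 RPKM, and ANT rose 1.79-fold. The 5 lower members, chosen after their values were seen, were TCP4, TCP2, TCP10, AT2G22840 and YAB3, genes of leaf growth and maturation. Whole seedlings were measured, so a change in the share of a tissue cannot be told from a change within it. The same limit holds for the photosynthesis genes and the cell type markers. Of 31 auxin response genes, 18 were higher and 2 lower (camera adjusted p = 0.000411, adjusted p = 0.596 with an estimated correlation). GH3.3, an auxin-conjugating enzyme gene, rose 5.70-fold, SAUR9 5.62-fold, IAA1 2.4-fold and the auxin efflux carrier gene PIN3 from 25.4 ± 0.648 to 50.7 ± 3.14 RPKM. With a filter at 5 RPKM, 11 of 15 auxin genes were higher. Of 22 ethylene genes, 11 were higher and 1 lower (camera adjusted p = 0.0107, adjusted p = 0.596 with an estimated correlation), including PR4, the receptor gene ETR2, the ACC oxidase gene AT1G62380 and EBP, which rose 2.51-fold, 2.36-fold, 2.3-fold and 1.8-fold. Of 19 gibberellin and brassinosteroid genes, 10 were higher and 2 lower (camera adjusted p = 0.0195, adjusted p = 0.596 with an estimated correlation). Among these, the gibberellin synthesis genes GA20OX2 and GA20OX1 rose 3.77-fold and 2.22-fold, the gibberellin-inactivating GA2OX2 rose 2.62-fold and the brassinosteroid synthesis gene BR6OX2 rose 2.03-fold. Of 9 mitochondrial stress genes, 6 were higher and none lower (camera adjusted p = 0.0119, adjusted p = 0.596 with an estimated correlation). CRF6 rose 5.79-fold, BCS1 5.45-fold, the transcription factor gene NAC13 2.83-fold and DIC2 1.40-fold. The counts in these 5 lists were equal when adjusted over the list alone. With a filter at 5 RPKM, camera no longer called the meristem list or the gibberellin and brassinosteroid list (adjusted p = 0.294 and 0.0565).

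**Figure D2:**
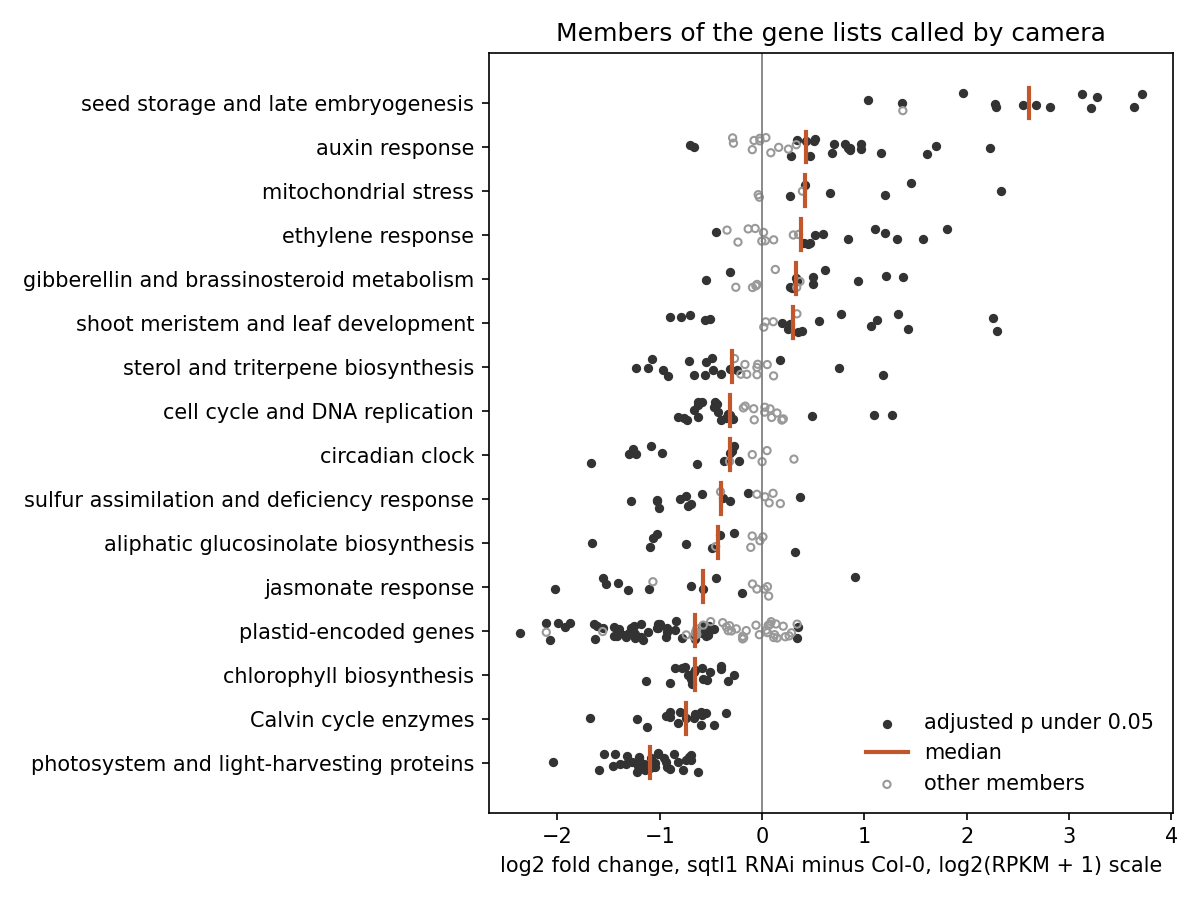
Log2 fold change (sqtl1 RNAi minus Col-0, log2(RPKM + 1) scale) of each tested member of the 16 gene lists called by camera. Filled points passed an adjusted p of 0.05, open points did not, vertical bars are list medians, and medians run from -1.098 for photosystem genes to 2.61 for seed genes.

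Circadian clock genes were lower. Of 17 tested, 12 were lower and none higher, or 13 lower adjusted over the list alone (camera adjusted p = 0.0019, adjusted p = 0.596 with an estimated correlation). PRR5 fell 3.34-fold, from 41.6 ± 0.517 to 12.5 ± 1.85 RPKM, and LNK1, FKF1 and GI fell 2.68-fold, 2.63-fold and 2.56-fold. CCA1, a morning-phased clock gene chosen after its values were seen, had a log2 fold change of 0.05 that did not pass the test. No series of hours over the day was measured, so these values cannot tell a lower level from a shift in timing. With no filter on low values, 7 of 19 clock genes were lower.

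Genes of sulfur assimilation, aliphatic glucosinolates, jasmonate, and sterols and triterpenes were lower. Of 19 sulfur assimilation genes, 12 were lower and 1 higher (camera adjusted p = 0.0119), with the ATP sulfurylase genes APS3 and APS1 2.28-fold and 1.66-fold lower, the APS reductase gene APR2 2.07-fold lower and the sulfate transporter gene SULTR4;2 1.88-fold lower. Of 14 aliphatic glucosinolate genes, 8 were lower and 1 higher (camera adjusted p = 0.0119). CYP79F1, which starts the core pathway, fell 6.95-fold, from 3.87 ± 0.437 to 0.557 ± 0.278 RPKM, and the side-chain elongation genes MAM1 and IPMI2 and the core gene CYP83A1 fell 2.18-fold, 2.15-fold and 1.69-fold. Of 17 jasmonate genes, 10 were lower and 1 higher (camera adjusted p = 0.0119). The jasmonate synthesis genes AOC2, LOX2 and AOS fell 4.11-fold, 3.12-fold and 2.55-fold, and the repressor gene TIFY7 fell 2.32-fold. Of 26 sterol and triterpene genes, 14 were lower and 3 higher (camera adjusted p = 0.0142). These included the root triterpene gene CYP71A16 and the sterol gene CYP710A1, 2.04-fold and 1.75-fold lower, and the squalene epoxidase genes SQE3 and XF1, 1.66-fold and 1.42-fold lower. The counts in these 4 lists were equal when adjusted over the list alone, and none was called with an estimated correlation (adjusted p = 0.596 for each). With a filter at 5 RPKM, camera no longer called the aliphatic glucosinolate list (adjusted p = 0.0641).

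Of 32 cell cycle and DNA replication genes, 18 were lower and 3 higher, or 4 higher adjusted over the list alone (camera adjusted p = 0.0256, adjusted p = 0.596 with an estimated correlation). This list was not called with a filter at 5 RPKM (adjusted p = 0.109). CYCD3;2, PLE, CYCA2;3 and CDC6 were 1.57-fold, 1.71-fold, 1.82-fold and 1.53-fold lower. The 3 higher members, chosen after their values were seen, were CYCB1;1 (AT4G37490), a mitotic cyclin gene also induced by DNA damage, which rose 2.4-fold, and the ribonucleotide reductase subunit genes TSO2 and RNR1, with log2 fold changes of 1.27 and 0.49.

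**Figure D3:**
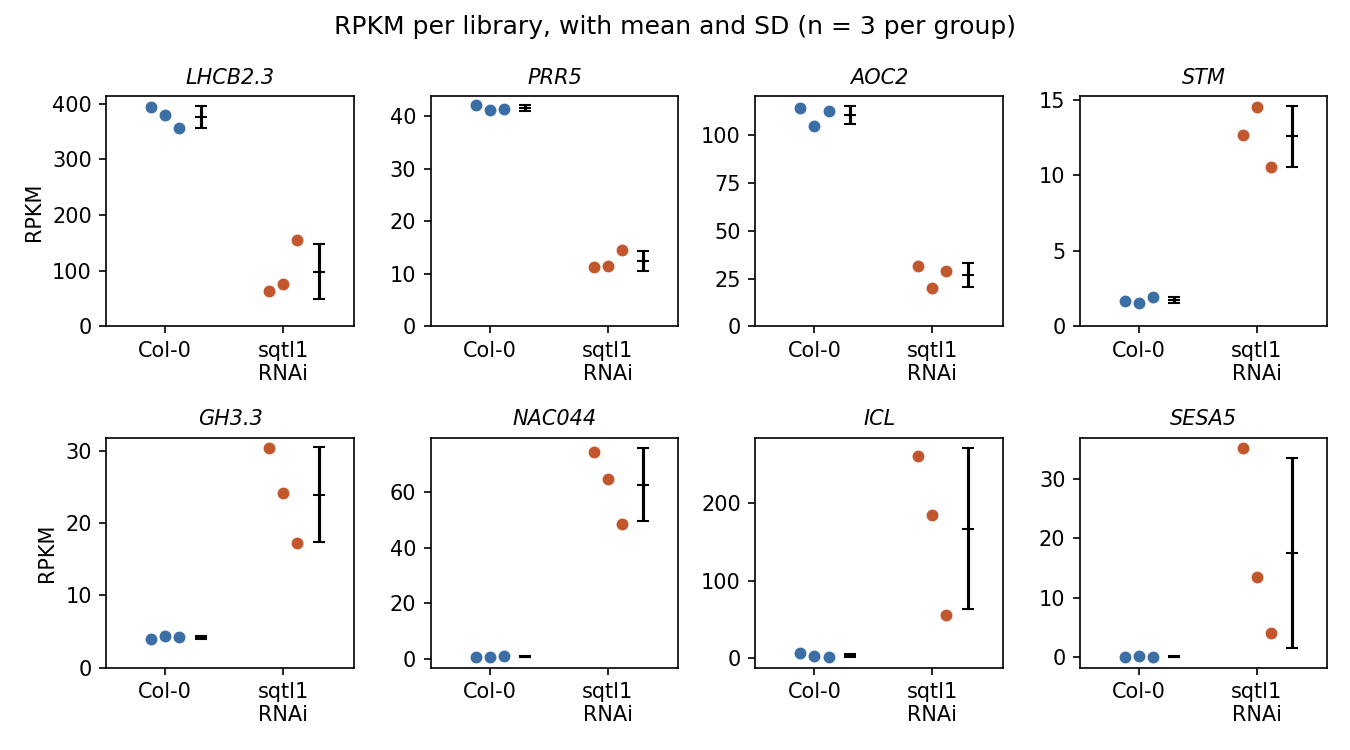
RPKM of 8 named genes in each library, on linear axes, with the mean and SD of each group (n = 3) beside the points. LHCB2.3, PRR5 and AOC2 lie lower and STM, GH3.3, NAC044, ICL and SESA5 higher in the RNAi libraries, and the spread of ICL (167 ± 104) and SESA5 (17.59 ± 16.0) is wide.

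The other 23 lists were not called by camera. The list of cytosolic ribosomal proteins held 25 higher and 14 lower genes of 47 (adjusted p = 0.082), and 26 and 14 adjusted over the list alone. Its rule matched gene symbols and so took in other genes. They were sorted by kind after their values were seen, and every member not given another kind was counted as cytosolic. By this sorting, 22 of 28 cytosolic ribosomal protein genes were higher and 1 lower. All 11 plastid ribosomal protein genes were lower, with log2 fold changes from -1.13 to -0.59. The lowest of the 28 was at -1.205, below each plastid member. The rule found 51 genes of all kinds, and whether it took in the whole cytosolic family was not checked. The lower genes named by the rule, RPL9, RPL12-C and RPL4, are of the plastid kind and were at 217 ± 4.08 against 98.7 ± 8.42, 410 ± 14.4 against 199 ± 19.1 and 291 ± 7.33 against 156 ± 15.7 RPKM. Of 15 flavonoid and anthocyanin genes, 6 were higher and 1 lower, 7 and 1 adjusted over the list alone (camera adjusted p = 0.0604), with GSTF12, the regulator TT8 and scpl10 rising 9.81-fold, 11.2-fold and 4.24-fold. The mean log2 difference of the list from Col-0 was 1.57, 0.84 and 0.079 in RNAi replicates 1 to 3. Its share of the library in replicate 3, 0.0191%, lay below each Col-0 library (0.0252% to 0.0304%), and without that replicate 10 of 15 members were higher.

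Organ and cell type markers went both ways within lists. Of 12 stomatal lineage and trichome genes, 2 were higher and 6 lower, 2 and 7 adjusted over the list alone (adjusted p = 0.151). TMM and EPF2, which pattern the stomatal lineage, fell to 0.507 ± 0.122 and 0.290 ± 0.0300 RPKM from 2.90 ± 0.181 and 2.07 ± 0.239, and ERL2 rose 3.91-fold. Of 25 root hair and epidermis genes, 5 were higher and 3 lower by both adjustments (adjusted p = 0.151), with GL2 and RSL2 lower and XTH13 higher. XTH13 did not pass without Col-0 replicate 3 (adjusted p = 0.057) or with no filter (adjusted p = 0.0625). Of the 25 root hair and epidermis genes, 0 were higher without Col-0 replicate 3 and 20 without RNAi replicate 3 (limma). The mean log2 differences of that list from Col-0 were 0.478, 0.552 and -0.145 in RNAi replicates 1 to 3. Of 19 genes of endodermis, stele and root meristem, 4 were higher and 10 lower, 5 and 12 adjusted over the list alone (adjusted p = 0.189), with CASP1 lower and CASP5 higher. Of 15 secondary wall and lignin genes, 2 were higher and 6 lower, 4 and 8 adjusted over the list alone (adjusted p = 0.18), with PAL2, XCP1 and XCP2 lower. Of 26 cell wall expansion genes, 12 were higher and 9 lower by both adjustments (adjusted p = 0.278), and EXP3, EXPA1 and XTH18 rose 3.27-fold, 2.55-fold and 2.72-fold. Of 18 flowering genes, 5 were higher and 6 lower by both adjustments (adjusted p = 0.664), with the floral repressor gene FLC 2.79-fold higher and AGL20 and SEP3 lower.

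In the nutrient lists, nitrogen metabolism had 2 higher and 11 lower of 25 genes (adjusted p = 0.104), with AMT1;1, GLU1 and CIPK3 lower. Phosphate starvation had 2 higher and 7 lower of 15 (adjusted p = 0.122), with the sulfolipid synthesis genes SQD1 and SQD2 lower and AT1G73010 4.58-fold higher. Both pairs of counts were equal adjusted over the list alone. Iron deficiency had 4 higher and 4 lower of 20, 4 and 3 adjusted over the list alone (adjusted p = 0.664), with the regulator gene FRU lower and OPT3 and NAS4 higher. The mean log2 differences of the iron list from Col-0 were -0.179, -0.191 and 0.039 in RNAi replicates 1 to 3. Sugar starvation and senescence had 4 higher and 3 lower of 22, 3 and 2 adjusted over the list alone (adjusted p = 0.873), with BCAT-2 5.82-fold higher, DIN9 1.78-fold higher and TPS11 lower. The RNAi libraries went opposite ways in this list, with mean log2 differences from Col-0 of -0.397, 0.132 and 0.363 in replicates 1 to 3. Genes of the mitochondrial genome had 7 lower and none higher of 25, 6 lower adjusted over the list alone (adjusted p = 0.107). They included ATMG00020, at 328 ± 15.6 against 186 ± 14.0 RPKM, and ATMG09450 and ATMG09730, which were listed with equal values and whose reads all map to several places. As for the plastid genome, the mitochondrial values are of RNA that passed poly(A) capture.

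In the stress and signalling lists, oxidative stress had 7 higher and 5 lower of 22 genes (adjusted p = 0.424), with the glutathione transferase gene GSTF6 5.46-fold and the catalase gene AT1G20620 2.47-fold higher, and the catalase gene CAT1 lower. Abscisic acid and dehydration had 7 higher and 10 lower of 24 (adjusted p = 0.508), with COR15B, COR47 and COR413-PM1 lower. Pattern-triggered immunity had 1 higher and 5 lower of 19 (adjusted p = 0.453), with YLS9 and WRKY11 lower and WRKY29 higher. Salicylic acid and systemic immunity had 4 higher and 6 lower of 14 (adjusted p = 0.739), with SAG101 2.00-fold higher, AIG1 rising from 0.117 ± 0.0503 to 4.68 ± 2.51 RPKM, and ALD1 lower. Cytokinin response had 1 higher and 5 lower of 17 (adjusted p = 0.424), with CKX4, ARR4 and ARR6 lower. Light signalling had 6 higher and 7 lower of 23 (adjusted p = 0.873), with PHYA and PIF3 2.07-fold and 2.38-fold higher and LZF1 lower. Heat shock had 1 higher and 3 lower of 14 (adjusted p = 0.878), with DREB2A, ROF2 and BAG6 lower. Endoplasmic reticulum stress had 4 higher and 4 lower of 15 (adjusted p = 0.92), with NAC103 rising 10.6-fold and ATERDJ3B and SDF2 lower. These 8 pairs of counts were equal adjusted over the list alone. Indolic glucosinolate and camalexin genes had 2 higher and 2 lower of 15, 1 and 2 adjusted over the list alone (adjusted p = 0.873), with PAD3 2.38-fold higher and CYP79B3 and UGT74B1 lower. The RNA silencing machinery had 7 higher and 3 lower of 21, 6 and 3 adjusted over the list alone (adjusted p = 0.122), with RDR1, AGO2 and AGO3 rising 1.87-fold, 1.66-fold and 2.17-fold. In the lists for salicylic acid, abscisic acid and indolic glucosinolates the median was negative and the mean positive, with camera's direction down, and for heat shock camera's direction was up and fry's down. Mean log2 differences from Col-0 also went opposite ways between RNAi replicates 1 and 3 for the indolic (-0.230 and 0.256), abscisic acid (0.178 and -0.205) and pattern-triggered immunity lists (-0.427 and 0.088). The salicylic acid (-0.048 and 0.215), heat shock (0.172 and -0.006) and light signalling lists (0.003 and -0.013) differed in sign as well.

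Of the 4 reference genes, ACT2 and PP2AA3 did not pass the test, at 374 ± 5.53 against 303 ± 43.0 and 22.2 ± 0.494 against 24.4 ± 1.56 RPKM (adjusted p = 0.0517 and 0.115). UBQ10 and the TIP41-like gene AT4G34270 were higher, at 726 ± 15.9 against 911 ± 27.9 and 22.5 ± 0.667 against 28.4 ± 0.624 RPKM (adjusted p = 0.0131 and 0.00196). Leaving out a library changed 3 of these calls. ACT2 passed without RNAi replicate 1 (adjusted p = 0.0441) or replicate 3 (0.00837), and PP2AA3 passed without RNAi replicate 3 (0.0212). ACT2 also passed with median-of-ratios rescaling (0.0496), quantile normalization (0.0313), a filter at 5 RPKM (0.0495) and no variance trend (0.0453). With library weights both ACT2 and PP2AA3 passed (0.000226 and 0.000787). UBQ10 did not pass without Col-0 replicate 1, 2 or 3 or RNAi replicate 2 (adjusted p = 0.0604, 0.0502, 0.0692 and 0.0595) or with no filter (0.0506), and quantile normalization moved its log2 fold change from 0.33 to 0.55.

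Camera called 16 of the 39 lists at the preset correlation. It called 0 with an estimated correlation, where 0 of 39 lists also had an unadjusted p under 0.05. Fry, which asks whether a list's genes move one way on balance and does not compare them with other genes, called 27. Its count depended on the libraries, with 13 without Col-0 replicate 3 and 30 without RNAi replicate 3.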

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

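Of 3219 values for the 192 named genes under the alternatives, 3193 kept their call, 17 lost it, 9 gained it and none reversed. Of the 10240 genes called, those that an alternative also tested kept their sign under it, except 7 under quantile normalization, and no rescaling moved the median log2 fold change over all genes by over 0.1. The genes higher numbered 7717 with library weights, against 4894, where the weights were dominated by 1 library (34.0 for RNAi replicate 2) and the fit of the weights did not converge. By at least 1 log2 unit, 238 genes were higher and 281 lower with a pseudocount of 5, which shrinks folds of low genes, 371 were higher with a filter at 5 RPKM, which tests fewer genes, and 975 were lower with voom weights, an alternative chosen after seeing the data whose cause was not tested. Leaving out 1 library gave 3515 to 5515 genes higher, 3975 to 6061 lower, 568 to 795 higher and 536 to 843 lower by at least 1 log2 unit, and 16 to 20 lists. Lists called numbered 0 with an estimated correlation, 27 by fry's directional test and 39 by its mixed test. Fry's directional test called 13 to 30 lists on leaving out 1 library, with the fewest without Col-0 replicate 3, and 11 with a replicate block. With a filter at 5 RPKM camera called 14 of 38 lists, of which 12 were among the 16. It no longer called the lists for aliphatic glucosinolates, cell cycle, gibberellins and brassinosteroids, and shoot meristem. With no filter it called 21, among them all 16. No pairing by replicate number was seen, since deviations of same-numbered libraries correlated at -0.064, 0.093 and 0.020 and not every library correlated best with its own number. With so few libraries per group, these correlations cannot exclude a pairing. With a replicate block 4272 genes were higher, 4762 lower and 17 lists called, and UBQ10 and AT3G06365 were the only named genes whose call changed (adjusted p = 0.0712 and 0.0748). In the 10 splits of the 6 libraries into 3 and 3, the real one is 1, so no share under 0.05 can be had. The real split gave 4894 genes higher and 5346 lower, 653 and 634 by at least 1 log2 unit, and the highest of the other splits was 0 for each in limma, with up to 367 genes at an unadjusted p under 0.05. The real split called 16 lists and the other 9 splits called 8 to 15, and each of these sets 2 Col-0 and 1 RNAi library against 1 and 2, so a part of the genotype difference stays in it. The genotype difference also widens the spread within both groups of such a split. The 0 genes called there are therefore no measure of false calls. The smallest simulated change was not recovered. The simulation changed a far smaller share of genes than was called in the data, and depth was not varied in it. It therefore cannot tell whether depth limits the recovery of such changes in the data.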

Other observations

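The lists for DNA damage, ribosome biogenesis, hypoxia, cutin and wax, and fatty acid breakdown, the transcript classes and the tests of explanations were chosen after seeing the data, whereas the annotation terms, the seed and auxin lists and the rescalings were planned. A list chosen this way can hold genes already seen to change, as the DNA damage list holds NAC044. The p values of these 5 lists and of the classes are therefore descriptive and no independent support. Genes of the DNA damage response were higher: 20 of 24 tested rose and none fell (median log2 fold change 0.76, camera p adjusted over these 5 lists = 4.79e-08, adjusted p = 0.253 with an estimated correlation). Besides NAC044, they included NAC085, at 0.0533 ± 0.0208 against 2.33 ± 0.429 RPKM, GMI1 and PARP2, which act in DNA repair and rose 18.4-fold and 5.96-fold, and the thymidine kinase gene TK1a, which rose 2.75-fold. The gene of the central regulator SOG1 had a log2 fold change of -0.14 that did not pass the test. Of 24 genes of ribosome biogenesis and the nucleolus, 23 rose (camera adjusted p = 4.79e-08, adjusted p = 0.253 with an estimated correlation). NUC-L2, the nucleolin variant, rose from 0.793 ± 0.103 to 12.3 ± 6.36 RPKM, FIB1 and NOP56 of the box C/D particle rose 1.86-fold and 2.13-fold, NAP57 rose 2.17-fold and the exosome subunit gene RRP41 rose 1.98-fold.

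Of 14 core hypoxia genes, 10 rose (camera adjusted p = 0.00054, adjusted p = 0.253 with an estimated correlation), with the haemoglobin gene HB1 9.72-fold and the plant cysteine oxidase genes PCO1 and PCO2 3.62-fold and 3.75-fold higher. Of 29 cutin and wax genes, 17 fell and 3 rose, 17 and 5 adjusted over the list alone (camera adjusted p = 0.00433, adjusted p = 0.253 with an estimated correlation). The epidermal regulator gene MYB106 fell from 2.47 ± 0.150 to 0.0567 ± 0.00577 RPKM, PEL3 fell from 12.7 ± 0.652 to 4.58 ± 0.582, and CER2 rose 1.91-fold. Among transcript classes, 70 of 132 small nucleolar RNA genes were higher and 6 lower, 53.0% higher against 25% of other genes (Fisher's exact test, two-sided, adjusted p = 4.67e-11). Only 4.55% were lower, against 27.6% of other genes (adjusted p = 4.67e-11). These values too are of RNA that passed poly(A) capture and may not follow the levels of the small nucleolar RNAs. The median share of their reads mapping to several places was 0.194. Fisher's exact test treats the genes as independent, which was not checked. Of 100 transposable element genes, 37 were higher and 11 lower, against 25.1% and 27.6% of other genes (adjusted p = 0.0104 and 0.000213). Primary microRNA transcripts were lower less often than other genes, 2 of 48 or 4.17% against 27.5% (adjusted p = 0.000163), and 15 were higher, 31.2% against 25.1% (adjusted p = 0.321). Of 22 transfer RNA genes none was higher and 11 were lower, against 25.2% and 27.4% of other genes (adjusted p = 0.0039 and 0.0324). The 11 all belong to the plastid and mitochondrial genomes, are counted in those lists too and share their limit from poly(A) capture. They include 2 pairs with equal values, and the median share of reads mapping to several places over the class was 0.676. Of 245 annotation terms, 7 were enriched among genes lower by at least 1 log2 unit, led by photosynthesis (29 of 66 genes, adjusted p = 3.33e-22 by Fisher's exact test) and lipid transport (17 of 68, adjusted p = 3.32e-08). Among the higher genes 0 terms passed, with 15 at an unadjusted p under 0.05.

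Transcripts of the ribosomal DNA unit rose, and most at 5.8S. On chromosome 3 of TAIR10.1, the 18S gene AT3G41768 (14197677 to 14199484) rose 2.21-fold, AT3G06355 (14199575 to 14200076), a noncoding RNA that spans the 5.8S gene and its flanks, rose 7.60-fold, and AT3G06365 further downstream (14200215 to 14204208) rose 1.41-fold, while on chromosome 2 18S (AT2G01010) rose 1.95-fold and 5.8S (AT2G01020) 11.6-fold. The call of AT3G06365 (adjusted p = 0.0269 in limma) was lost without Col-0 replicate 1, 2 or 3 or RNAi replicate 2 (0.0836, 0.105, 0.0735 and 0.0812) and with no filter (0.24), whereas quantile normalization raised its log2 fold change from 0.49 to 1.1 (adjusted p = 0.000744) and that of 18S AT3G41768 from 1.13 to 1.75. Within each unit the fold of the 5.8S feature was at least 2.97 times the 18S fold in each RNAi library (2.47 with quantile normalization). This argues against carry-over of ribosomal RNA past poly(A) selection as the whole cause only if carry-over raises 18S and 5.8S alike. Whether it does was not tested. The units are also not measured apart, since the share of reads of AT2G01020 mapping to several places was 0.975. Reads moved between copies would leave their sum in place. Reads were summed over the features that hold the 5.8S sequence, AT2G01020, AT3G06355 and the 5.8S gene AT3G41979, which held no reads in either group. The sum rose at least 8.70-fold in each RNAi library. A hypothesis that stays open is that adenylated precursors or by-products of 5.8S processing may build up in the RNAi line: 53.0% of small nucleolar RNA genes, whose products are trimmed in a like way, were higher, but the values per gene give no coverage along the unit.

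The seed transcripts could stem from ungerminated seeds among the RNAi seedlings. One source of fixed make-up would give all 13 called members the same ratio of gains in RNAi replicates 1 and 2, whereas this ratio ran from 1.06 for LTP2 to 8.61 for CRU3, an 8.09-fold range, or 6.56-fold without LTP2. The ratio of gains in replicates 1 and 3 was less spread. It was 1.61 for LTP2 and ran from 4.27 for PER1 to 10.6 for SESA3 over the other members, so the evidence against such a source is weaker there. Scaling of the libraries was argued against by a list median of at least 2.44 under both rescalings. Several sources of different make-up, such as seeds and slow seedlings, stay open. A younger stage of the RNAi seedlings also stays open: 10 of 20 genes of fatty acid breakdown and the glyoxylate cycle were higher and 1 was lower, 10 and 2 adjusted over the list alone (camera adjusted p = 0.00597, adjusted p = 0.253 with an estimated correlation), but no series of stages was measured.

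RNAi replicate 3 lay nearest to Col-0. The test for Col-0 RNA mixed into it takes replicate 3 to be otherwise like the mean of replicates 1 and 2. Genes that rose and genes that fell would then give the same Col-0 share. Among 189 genes that rose at least 4-fold in RNAi replicates 1 and 2 the median share was 0.440, and among 65 that fell at least 4-fold it was 0.136, a difference of 0.30 with quartiles of 0.256 to 0.696 and 0.054 to 0.193. This argues against mixing alone. Mixing together with a spread between samples is not excluded, since the genes were picked on replicates 1 and 2, which also differed. Replicate 1, which lay farthest from Col-0, had 43.7 M estimated reads and replicate 3 had 43.9 M, too near each other to rank. A weaker effect of the RNAi in that sample (first component score 21.7) may account for a part of this and could not be tested without the target, but an effect weaker by the same share in every list goes against the values: auxin genes rose most in replicate 3 (0.383, 0.452 and 0.58 log2 units in replicates 1 to 3), cutin and wax genes fell most there (-0.283, -0.378 and -0.469), and the second component sets the replicates apart (21.9, -5.5 and -24.8).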
